A study of Mus musculus with 23 samples.

How the data were processed

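The deposited series held bulk RNA sequencing of 23 libraries of sorted mouse mTECs, in a WT and an Aire KO group for each of the mTEChi and mTEClo gates. Per the labels, total RNA was converted with oligo dT and not-so-random primers, and libraries were made with the Tn5 transposase, which keeps no strand information. Overlapping genes and near-identical copies can therefore exchange reads, and their counts are uncertain. Sex, age in weeks and a replicate number were given for each library. The labels do not say whether libraries were made from separate animals, nor what the replicate numbers pair.

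The table used here holds counts per Ensembl gene as deposited by the authors, 1 column per library, for 53402 gene identifiers. Per the submitters' processing notes the tools were fastp 0.20.0, STAR 2.7.3a, SAMtools 1.9, Picard 2.21.1, HTSeq 0.11.2 and edgeR without a version, on the builds mm10 and GRCm38, and the notes give no role or order for them. A normalized table deposited by the authors has the unit signal and 20236 genes. Each of its values was the count divided by 1 factor per library, with a largest difference of 1.9e-11. The factors lay between 0.925 and 1.05 of the library totals on the CPM scale, the scaling behind them is not stated, and 27 genes tested here were not in it. That table was used in an alternative only.

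Library totals ranged from 1628778 to 3883437 counts in WT mTEClo and from 1639231 to 3938588 in KO mTEClo. In WT mTEChi they ranged from 1602125 to 3231079 and in KO mTEChi from 2528049 to 3106026. A gene listed at 0 in all libraries of a group was given the limit of 3 counts over the group, and a fold against it is given as a lower bound. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Gene positions and types were taken from GENCODE of the same build, and of 53402 identifiers 53316 had a symbol.

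Genes were filtered with filterByExpr by group (minimum count 10), which left 19310. TMM factors, dispersions and quasi-likelihood fits were made in edgeR 4.0.16 (R 4.3.3) with robust estimation, over all 23 libraries in 1 fit with a term for each group and for sex. The contrasts were KO against WT in each gate, mTEChi against mTEClo in each genotype, the difference between the KO effects of the gates, and female against male within WT. Because all KO libraries were male, the sex term rested on WT libraries alone. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its contrast. The SE of a log2 change was taken as its size divided by the square root of the F statistic. CPM were computed with the TMM factors, and principal components over the 2000 most variable genes of log2 CPM with a prior count of 2.

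Gene lists were written from general knowledge of the field. There were 41 lists with 745 symbols, of which 742 matched a gene, and the 39 with at least 3 tested members were tested. They held antigens often cited as Aire-dependent, Fezf2-dependent or Aire-independent, and genes of salivary and lacrimal gland, pancreas, liver, prostate and seminal vesicle, milk, retina and lens, neurons and glia, intestine and stomach, kidney and endocrine organs, lung, and testis and sperm. Others held genes of tuft, microfold, ciliated, muscle, keratinocyte, neuroendocrine, ionocyte, entero-hepato and lung and secretory mimetic mTECs. The rest held MHC class II and maturation, CCL21 mTEClo, chemokine and cytokine, Aire partner, NF-kB, interferon-stimulated, cell cycle, dissociation stress, mitochondrially encoded and housekeeping genes. Markers of thymocytes, B cells, dendritic cells and macrophages, fibroblasts, endothelium and cTECs were tested too, and red blood cell and major urinary protein genes were listed but too few were measured. Lists were tested against all other tested genes with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists of a contrast), then with an estimated correlation and with fry.

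The genes named were chosen by a rule. For KO against WT in each gate and for the gates in WT, it took Aire in every library. It then took the 10 largest falls and rises among genes that passed, with a mean of at least 5 CPM in the higher group and every library of it above those of the lower group, and left out gene models without a name. It added members with the smallest p from up to 8 passing lists and from each list of other cell types, and 8 fixed genes, Aire, Fezf2, Ins2, Mucl2 (listed as Spt1), Cd80, Ccl21a, Gad1 and Crp. For the other contrasts it took the 3 genes with the smallest p in each direction. The rule allowed up to 3 members per list. The numbers used, 2 per list and 1 per marker list, were set after values were seen. So was a repeat of the largest falls and rises in KO mTEChi without the genes that split with 6 libraries. Of the genes the rule names, 1 is not reported here.

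Alternatives set beforehand were an adjusted p under 0.01, a change of over 2-fold as well, RLE and upper quartile factors, no filter, and CPM above 1 in at least 4 libraries. Other tools were DESeq2 1.42.0, limma-voom with quality weights, and limma with trend on log2(value + 1) of the deposited normalized values. Fits without sex, with sex and age, of males alone, of 5-week males alone, with the replicate number as a block, of the groups compared alone, and without each library in turn were set then too. Alternatives added after seeing the data were the merging of close library pairs, fits without 6 libraries that held no mitochondrial counts, a term for these libraries with and without age, the removal of 42 genes that split with them, and list tests among 5-week males. Close pairs were libraries of the same group, sex and age with a biological coefficient of variation (BCV) under 0.08. There were 9, with BCVs of 0.0335 to 0.0680, against 0.0653 to 0.328 in the other 52 pairs within groups, which differed in sex, age or BCV.

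In fits to simulated data with only 66 or 67 genes changed per fold size, 2.07 to 8.02% of calls were false, and 0 of 20 random lists passed per contrast. These rates may not hold here. Detection was also compared after scaling every library to 1590514 counts, with exact two-sided permutation tests of group means. The replicate number was not used as a block in the reported fit, since several WT libraries of equal number differ in sex or age between the gates, although all KO libraries of equal number match. Age was not fitted because KO libraries were from mice of 5 and 6 weeks and WT libraries from mice of 4 and 5 weeks. Reads, strand and isoforms were not analysed here.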

Results

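Total RNA of medullary thymic epithelial cells (mTECs) of C57BL/6 mice was sequenced in 23 libraries. mTECs present peptides of genes otherwise restricted to peripheral tissues to developing T cells, and Aire is the nuclear regulator known to act on such genes in them. Cells negative for DAPI, CD45 and Ly51 and positive for EpCAM had been sorted into a population high for MHC class II (mTEChi) and a low one (mTEClo). The libraries formed 4 groups, with 8 of WT mTEClo, 4 of Aire KO mTEClo, 7 of WT mTEChi and 4 of Aire KO mTEChi. The WT mTEClo libraries were labelled male in 5 cases and female in 3, and 5 of the 8 were from mice of 4 weeks and 3 from mice of 5 weeks. The WT mTEChi libraries were labelled male in 5 cases and female in 2, 2 of them from mice of 4 weeks and 5 from mice of 5 weeks. All KO libraries were male, and in each gate 2 were of 5 weeks and 2 of 6 weeks.

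In the order of the replicate numbers, the libraries of WT mTEClo held 1804090, 1628778, 3883437, 3749071, 3851539, 3255607, 2998595 and 3369652 counted reads. Those of KO mTEClo held 1883769, 1639231, 3272356 and 3938588, those of WT mTEChi 1602125, 1655955, 2750800, 3201804, 3231079, 3007969 and 2718749, and those of KO mTEChi 2528049, 2701119, 3106026 and 2574254. The floor of 3 counts over a group corresponded to 0.122, 0.275, 0.161 and 0.299 CPM (counts scaled to a common library total with edgeR) in WT mTEClo, KO mTEClo, WT mTEChi and KO mTEChi. Intervals and floors cover counting error only. Group values are mean CPM ± SD over libraries, and log2 changes are given ± SE. Fitted changes of genes at or near 0 in a group depend on a prior count and are no bounds. Gene p-values measure spread between samples not labelled as separate animals. List p-values compare members with other genes. The groups, covariates and tests of these comparisons, the gene lists and the rule for named genes, apart from its numbers per list, were fixed before the data were examined.

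**Figure D1:**
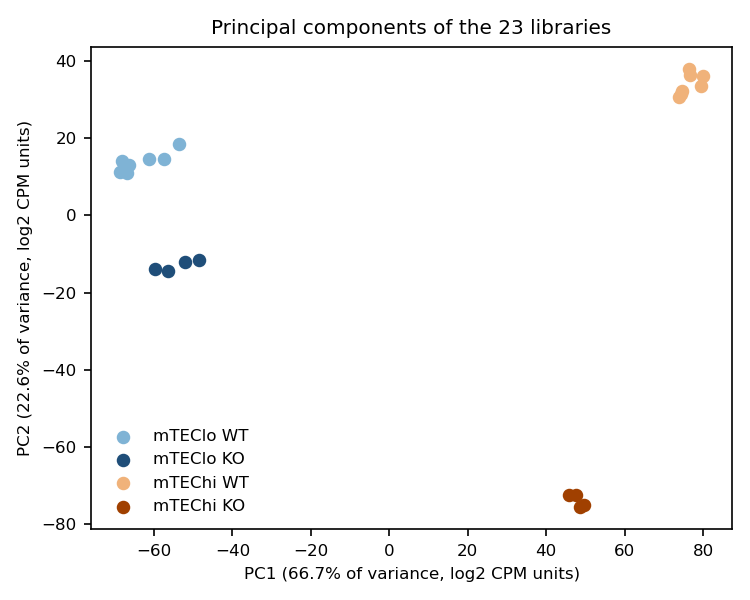
Principal component scores (log2 CPM, arbitrary units) of the 23 libraries over the 2000 most variable genes, with colours for the 4 groups. The first axis held 66.7% and the second 22.6% of the variance, and the 4 groups lay apart on them. On the fourth axis, not drawn, replicates 1 and 2 of KO mTEClo (scores -25.7 and -29.8) lay apart from 3 and 4 (11.7 and 14.5).

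Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610 of GRCm38) was counted in every library of both gates but 1. In WT mTEChi its levels were 825, 821, 921, 818, 831, 757 and 753 CPM, and in KO mTEChi 39.05, 39.3, 21.6 and 17.1 CPM. In WT mTEClo they were 82.1, 82.04, 34.9, 53.5, 19.6, 128, 80.3 and 73.2 CPM, and in KO mTEClo 7.58, 3.13, 0 and 0.243 CPM. Replicate 3 of KO mTEClo, listed at 0, was the library without a count of it. The mean fell from 818 ± 56.02 CPM (n = 7) to 29.3 ± 11.6 CPM (n = 4) in mTEChi, a log2 change of -4.87 ± 0.46, adjusted p = 5.6e-08. In mTEClo it fell from 69.2 ± 33.4 CPM (n = 8) to 2.74 ± 3.53 CPM (n = 4), a log2 change of -5.20 ± 0.70, adjusted p = 3.0e-05. Every KO library lay below every WT library of its gate.

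**Figure D2:**
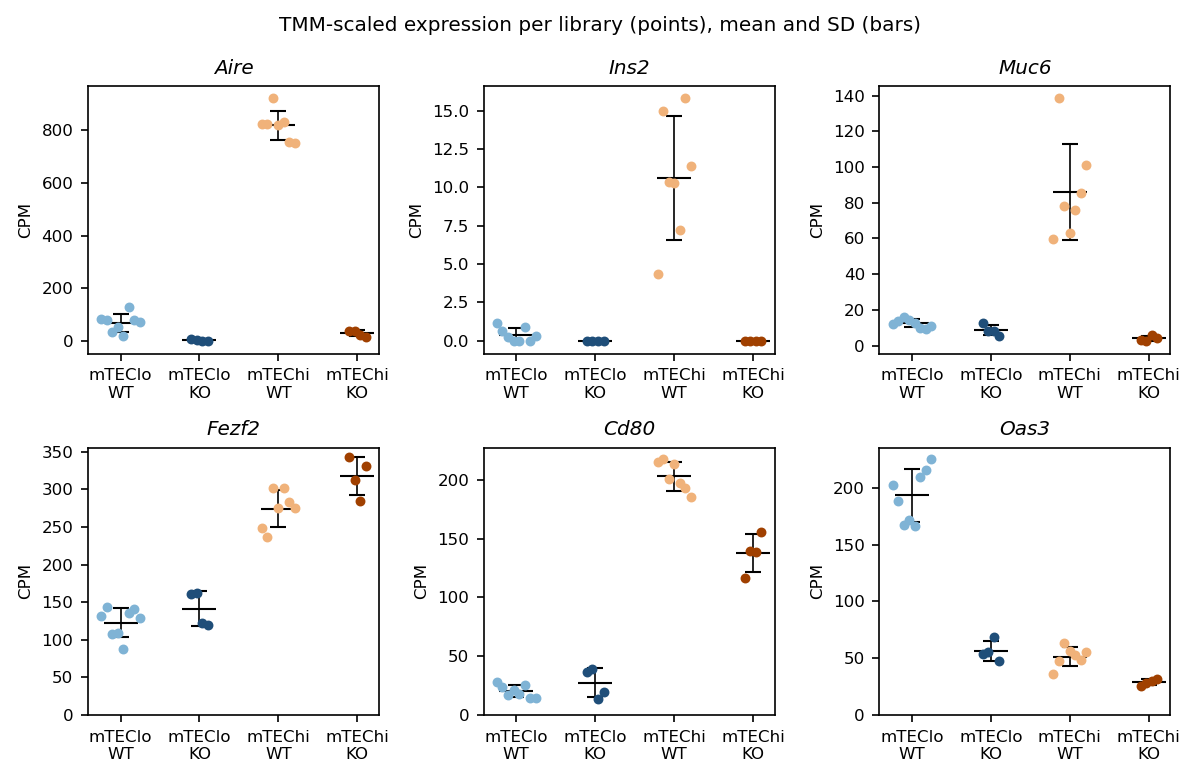
Level in CPM of Aire, Ins2, Muc6, Fezf2, Cd80 and Oas3 in each library (points), by group, with the mean and SD of each group (bars). Muc6 averaged 85.98 CPM in WT and 3.97 CPM in KO mTEChi, while the Fezf2 means were 275 and 318 CPM.

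The comparison of KO with WT mTEChi asks what Aire does to transcription in the cells that express most of it. Without Aire, genes known from peripheral tissues fell far, while the thymic regulator Fezf2 did not pass the test. Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381), which encodes insulin, stood at 10.6 ± 4.05 CPM in WT (n = 7) and was listed at 0 in KO mTEChi (n = 4), at least 35.6-fold lower (adjusted p = 5.0e-08). The salivary protein gene Mucl2 (ENSMUSG00000036925, chromosome 15, 103895855 to 103899312) went from 27.2 ± 4.85 to 0.214 ± 0.247 CPM, 133-fold (95% counting interval 36.7 to 1102) lower with adjusted p = 2.1e-11. The gastric mucin Muc6 (ENSMUSG00000048191, chromosome 7, 141633456 to 141655319) fell from 85.98 ± 27.1 to 3.97 ± 1.63 CPM, a log2 change of -4.47 ± 0.26, adjusted p = 2.0e-13. The T cell inhibitory receptor gene Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832) rose from 15.6 ± 3.78 to 133 ± 38.3 CPM, a log2 change of 2.98 ± 0.24, adjusted p = 1.5e-10.

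Genes of secretory organs fell together. Of the antigens often cited as Aire-dependent, 8 of 9 measured members fell and 0 rose (8 and 0 adjusted over the list alone), with a median log2 change of -6.70, or -4.21 with members at 0 at their bound (adjusted p = 1.7e-06; 0.002 with an estimated correlation). Among salivary and lacrimal gland genes, 9 of 10 measured members fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -5.75, or -4.18 with members at 0 at their bound (adjusted p = 3.0e-06; 0.002 with an estimated correlation). Dcpp1, a salivary protein gene of both lists, was 62.5-fold (95% counting interval 11.002 to 2490.4) lower. Among pancreas genes, 14 of 17 measured members fell and 1 rose (15 and 1 adjusted over the list alone), with a median log2 change of -3.77 (adjusted p = 4.5e-06; 0.018 with an estimated correlation). Zg16, a lectin of secretory granules, was at least 48.99-fold lower, and the gut peptide gene Pyy was 121-fold (95% counting interval 33.2 to 999.95) lower. Among liver genes, 17 of 26 measured members fell and 3 rose (17 and 3 adjusted over the list alone), with a median log2 change of -2.89 (adjusted p = 1.6e-06; 0.014 with an estimated correlation). Itih3 and Itih4, which encode plasma proteins of the inter-alpha-trypsin inhibitor family, fell by log2 changes of -5.56 ± 0.43 and -5.16 ± 0.34.

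Among intestine and stomach genes, 20 of 27 measured members fell and 0 rose (20 and 1 adjusted over the list alone), with a median log2 change of -4.04 (adjusted p = 4.2e-08; 0.0096 with an estimated correlation). Pgc, which encodes the precursor of a gastric protease, fell from 80.9 ± 18.8 to 1.04 ± 0.706 CPM. In the milk list, 4 of 6 measured members fell and 0 rose (4 and 0 adjusted over the list alone), with a median log2 change of -3.48 (adjusted p = 0.0083; 0.039 with an estimated correlation). Of kidney and endocrine organ genes, 10 of 15 measured members fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 change of -2.22 (adjusted p = 4.3e-04; 0.034 with an estimated correlation). For prostate and seminal vesicle genes, 11 of 15 measured members fell and 0 rose (11 and 0 adjusted over the list alone), with a median log2 change of -1.76 (adjusted p = 3.9e-04; 0.12 with an estimated correlation). In retina and lens, 11 of 15 measured members fell and 0 rose (11 and 0 adjusted over the list alone), with a median log2 change of -1.07 (adjusted p = 0.0077; 0.12 with an estimated correlation). For neurons and glia, 10 of 16 measured members fell and 2 rose (10 and 2 adjusted over the list alone), with a median log2 change of -1.18 (adjusted p = 0.0083; 0.15 with an estimated correlation). In lung, 5 of 7 measured members fell and 1 rose (5 and 1 adjusted over the list alone), with a median log2 change of -2.49 (adjusted p = 0.024; 0.12 with an estimated correlation).

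The antigens often cited as Fezf2-dependent did not pass as a list, with 5 lower and 3 higher of 12, or 5 and 4 adjusted over the list alone and adjusted p = 0.88. Fezf2 (ENSMUSG00000021743, chromosome 14, 12342094 to 12348189), a transcription factor of mTECs, stood at 275 ± 24.9 CPM in WT and 318 ± 25.2 CPM in KO, a log2 change of 0.21 ± 0.12, adjusted p = 0.13. The list cited as Aire-independent had 4 lower and 2 higher of 7, or 4 and 2 adjusted over the list alone (adjusted p = 0.28). In it Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), an enzyme of GABA synthesis, fell by 0.60 on the log2 scale (SE 0.14, adjusted p = 9.1e-04). Crp (ENSMUSG00000037942, chromosome 1, 172698055 to 172833031), an acute phase protein of liver, rose by 0.62 (SE 0.20, adjusted p = 0.01), a call that ended with age in the fit (adjusted p = 0.19). Testis and sperm genes had 3 higher and 1 lower of 7, or 3 and 2 adjusted over the list alone (adjusted p = 0.72). Of 15 housekeeping genes 12 did not pass (adjusted p = 1).

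The largest falls outside the genes that split with 6 libraries, described below, held several tissue products. The surface mucin Muc16, the oesophageal keratin Krt13 and the muscle myosin Myh8 were listed at 0 in KO, at least 214-fold, 192-fold and 138-fold lower. Cyp1a2, a liver enzyme of drug oxidation, and Gstm3, a glutathione transferase, were at least 162-fold and 123-fold lower. The intestinal mucin Muc2 went from 116 ± 17.2 to 0.0856 ± 0.171 CPM, 1164-fold (95% counting interval 209 to 45982) lower. Lefty2, a signal of left-right patterning, the calcium-binding protein Calb2 and the gut lectin Reg3b were at least 124-fold, 132-fold and 99.7-fold lower. The hormone gene Sst was at least 94.2-fold lower, although among 5-week males, at 31.4 to 35.8 CPM in 3 WT and 0 in 2 KO libraries, it did not pass (adjusted p = 0.11).

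Of the lists for mTECs that mimic peripheral cell types several fell, and of these only the ionocyte list passed with an estimated correlation. Among ionocyte genes, 10 of 12 measured members fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 change of -3.19 (adjusted p = 8.5e-05; 0.018 with an estimated correlation). Foxi1, the regulator of ionocytes, fell from 19.1 ± 4.21 to 0.402 ± 0.0417 CPM, and the ion transporter Slc12a2 from 102 ± 15.9 to 35.5 ± 0.886 CPM. Among ciliated cell genes, 12 of 20 measured members fell and 1 rose (12 and 1 adjusted over the list alone), with a median log2 change of -2.02, or -1.17 with members at 0 at their bound (adjusted p = 3.9e-04; 0.12 with an estimated correlation). Of lung and secretory genes, 13 of 17 measured members fell and 1 rose (13 and 1 adjusted over the list alone), with a median log2 change of -3.22 (adjusted p = 3.9e-04; 0.15 with an estimated correlation). For keratinocyte genes, 12 of 24 measured members fell and 2 rose (12 and 2 adjusted over the list alone), with a median log2 change of -0.81 (adjusted p = 0.0049; 0.33 with an estimated correlation). In the muscle list, 14 of 23 measured members fell and 2 rose (14 and 3 adjusted over the list alone), with a median log2 change of -1.10 (adjusted p = 0.006; 0.28 with an estimated correlation). In the neuroendocrine list, 10 of 17 measured members fell and 1 rose (10 and 1 adjusted over the list alone), with a median log2 change of -0.98 (adjusted p = 0.0083; 0.23 with an estimated correlation). In the entero-hepato list, 14 of 20 measured members fell and 2 rose (14 and 2 adjusted over the list alone), with a median log2 change of -1.86 (adjusted p = 0.0072; 0.25 with an estimated correlation). The tuft list (7 lower and 3 higher of 23, or 7 and 3 adjusted over the list alone, adjusted p = 0.19) and the microfold list (5 lower and 2 higher of 13, or 5 and 3 adjusted over the list alone, adjusted p = 0.5) did not pass.

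Interferon-stimulated genes fell. Of these 22 of 27 measured members fell and 2 rose (22 and 2 adjusted over the list alone), with a median log2 change of -0.81 (adjusted p = 1.6e-06; 0.018 with an estimated correlation). Ifit2, a sensor of viral RNA, fell from 48.003 ± 9.46 to 2.73 ± 1.996 CPM, and the GTPase gene Gbp2 from 40.99 ± 4.97 to 10.6 ± 0.468 CPM. The 2 members that rose, named after their values were seen, were the transcription factor Irf1 (0.45 ± 0.07) and Usp18 (0.35 ± 0.081), which removes the ubiquitin-like ISG15 tag from proteins.

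Genes of MHC class II and mTEChi maturation rose, and 11 of 20 measured members rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.46 (adjusted p = 0.0036; 0.31 with an estimated correlation). The member that fell, Cd80 (ENSMUSG00000075122, chromosome 16, 38455561 to 38496335), a ligand that costimulates T cells, went from 203 ± 12.3 to 138 ± 16.04 CPM, a log2 change of -0.62 ± 0.16, adjusted p = 0.0026, with adjusted p = 0.067 when age was fitted. Genes of the NF-kB pathway rose too, and 12 of 20 measured members rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.42 (adjusted p = 0.0014; 0.25 with an estimated correlation). The member that fell, named after its value was seen, was the inhibitor Tnfaip3 (-0.74 ± 0.085). Chemokine and cytokine genes had 11 lower and 4 higher of 18, or 11 and 4 adjusted over the list alone, without passing (adjusted p = 0.35). The lists of Aire partners (adjusted p = 0.67), CCL21 mTEClo genes (adjusted p = 0.35), cell cycle (adjusted p = 0.15) and dissociation stress (adjusted p = 0.34) did not pass. Ccl21a (ENSMUSG00000094686, chromosome 4, 42772860 to 42773993), a chemokine of mTEClo with near-identical copies, stood at 7.99 ± 1.77 CPM in WT and 7.96 ± 1.68 CPM in KO.

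Among the largest rises outside the split genes were Ptchd4, a membrane protein of the Patched family, from 17.4 ± 2.41 to 145 ± 35.5 CPM, and the acetyl-CoA hydrolase gene Acot12, from 7.36 ± 1.87 to 64.3 ± 11.2 CPM. Rgr, an opsin of the retinal epithelium, rose from 6.95 ± 2.92 to 54.1 ± 6.99 CPM and the immune receptor gene Nfam1 from 6.89 ± 1.82 to 61.4 ± 10.6 CPM. Fam19a1 and H2-Pb rose by log2 changes of 2.88 ± 0.23 and 2.94 ± 0.39. The antisense transcript Ptgs2os2, the olfactory receptor Olfr1138 and AY761185, a defensin-like gene with near-identical copies, rose from means of 1.20, 0.897 and 0.425 CPM to 10.6, 9.92 and 16.3 CPM. With a term for the 6 libraries Ptgs2os2 in KO vs WT in mTEChi turned to log2 -2.14.

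Markers of other cell types were read as well, although the sort for EpCAM and against CD45 and Ly51 would remove most such cells. In the fibroblast list, 8 of 13 measured members fell and 1 rose (8 and 4 adjusted over the list alone), with a median log2 change of -1.16 (adjusted p = 0.026; 0.12 with an estimated correlation). The matrix gene Fbn1 fell from 103 ± 11.7 to 35.9 ± 3.35 CPM. In the endothelium list, 6 of 9 measured members fell and 1 rose (6 and 1 adjusted over the list alone), with a median log2 change of -1.28 (adjusted p = 0.024; 0.12 with an estimated correlation). Plvap, a protein of vessel walls, fell from 21.96 ± 7.16 to 0.685 ± 0.464 CPM. The endothelium list in KO vs WT in mTEChi lost its call without WT mTEChi replicate 2, 3, 5 or 7, at adjusted p of 0.06, 0.072, 0.07 and 0.078. The dendritic cell and macrophage list (11 lower and 3 higher of 16, or 11 and 3 adjusted over the list alone, adjusted p = 0.085) did not pass, and its member Adgre1 fell from 37.2 ± 5.66 to 0.902 ± 0.850 CPM. Nor did the B cell (5 higher and 2 lower of 9, or 5 and 2 adjusted over the list alone, adjusted p = 0.14) or thymocyte list (1 higher and 5 lower of 12, or 1 and 5 adjusted over the list alone, adjusted p = 0.42), in which the B cell kinase gene Blk rose from 18.9 ± 2.71 to 87.3 ± 21.7 CPM and the T cell factor Tcf7 from 130.4 ± 9.68 to 265 ± 53.3 CPM. The list of cortical epithelium (cTEC) had 6 higher and 4 lower of 12, or 6 and 4 adjusted over the list alone (adjusted p = 0.58), and its gene Enpep, a peptidase that is the Ly51 antigen of the sort, fell from 45.4 ± 9.07 to 2.89 ± 1.80 CPM. Of the red blood cell list only Slc4a1 and Alas2 were measured, too few for a test, and Slc4a1, the red cell anion exchanger, was at least 63.1-fold lower. Of the major urinary proteins only Mup4 (log2 change -6.93 ± 0.95) and Mup6 (-7.33 ± 1.06) were measured, and both fell.

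All 4 KO mTEChi libraries and replicates 3 and 4 of KO mTEClo held 0 counts of mitochondrial genes, against 0.261 to 0.527% of counts in the other 17 libraries. Along this division 42 genes split, whose CPM in all 6 lay over 2-fold above or below those in all 17 others, 14 higher and 28 lower. They held 9 mitochondrial genes, among them the ribosomal RNA mt-Rnr2, which averaged 919 ± 288 CPM in WT mTEChi. They also held the Mediator subunit Med10 (76.4 ± 8.86 CPM in WT mTEChi and listed at 0 in KO) and, upward, Brms1, Ubxn6, Chtf8, Fam220a, Sssca1, B4gat1 and the chemokine gene Ccl19. Brms1 went from 0.368 ± 0.289 to 50.4 ± 3.52 CPM. For these genes genotype and this split of the libraries were the same division in mTEChi. In the mitochondrially encoded list 7 of 7 measured members fell and 0 rose (7 and 0 adjusted over the list alone), with a median log2 change of -12.94, or -10.13 with members at 0 at their bound (adjusted p = 9.6e-05; 0.23 with an estimated correlation).

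**Figure D3:**
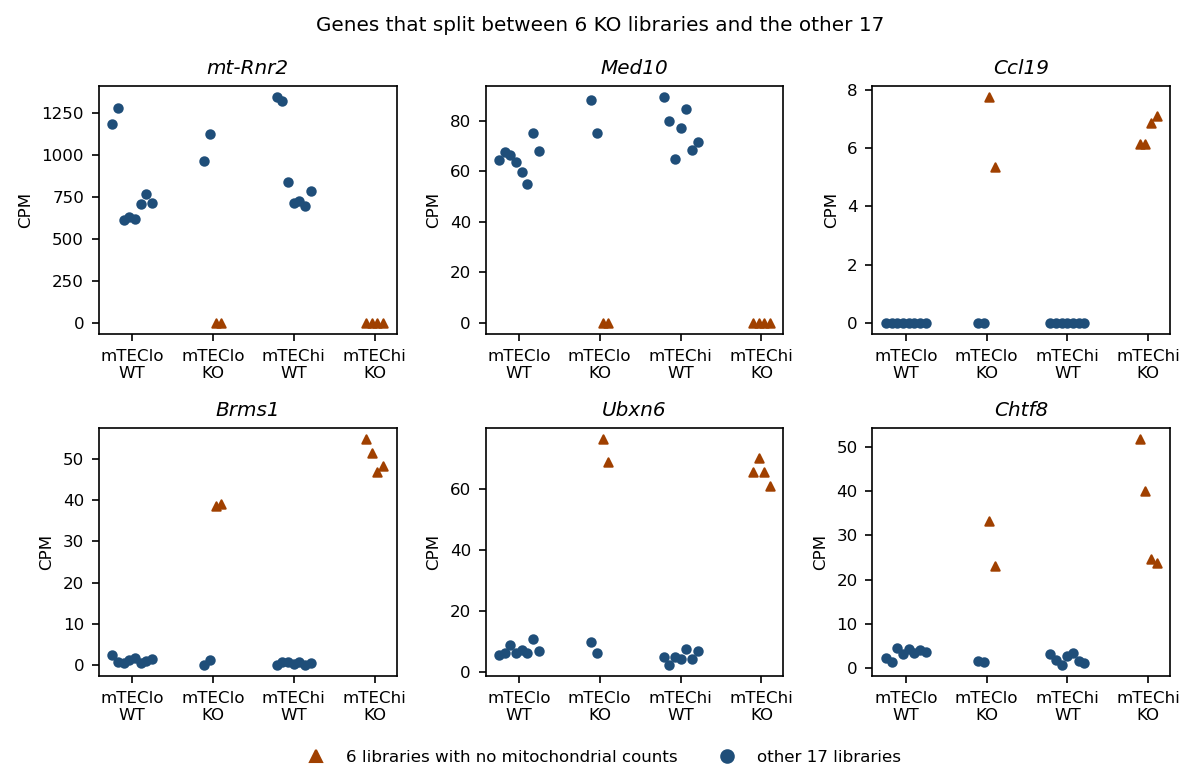
Level in CPM of mt-Rnr2, Med10, Ccl19, Brms1, Ubxn6 and Chtf8 in each library, with triangles for the 6 libraries that held no mitochondrial counts and circles for the other 17. Med10 was at 0 in the 6 and at a mean of 76.4 CPM in WT mTEChi, and Ccl19 was at 0 in the 17.

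In edgeR's quasi-likelihood test 10366 of 19310 tested genes changed (53.7%), 4966 upward and 5400 downward. By over 2-fold, 1111 rose and 3381 fell, and by over 8-fold 29 rose and 1225 fell. Of 39 tested lists 24 passed, 2 upward and 22 downward, 9 of them also with an estimated correlation. Median, mean and test differed in sign for the testis, housekeeping, Aire partner and cTEC lists. With upper quartile factors 3913 rose and 6222 fell. Among 5-week males alone 9558 genes changed, with close library pairs merged 8497 and with the replicate number as a block 10032. A term for the 6 libraries, which rests on KO mTEClo alone, along the division of age, gave 6872 genes changed, 5224 of them called the same way without it. It turned the value of Aire in KO vs WT in mTEChi (log2 change 0.088), of Cd80, of Crp and of Ptgs2os2 to the other sign, turned the cell cycle list in KO vs WT in mTEChi upward (adjusted p = 9.5e-07), and ended the calls of many other named genes and of the retina and lens, lung, muscle, entero-hepato and mitochondrial lists.

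**Figure D4:**
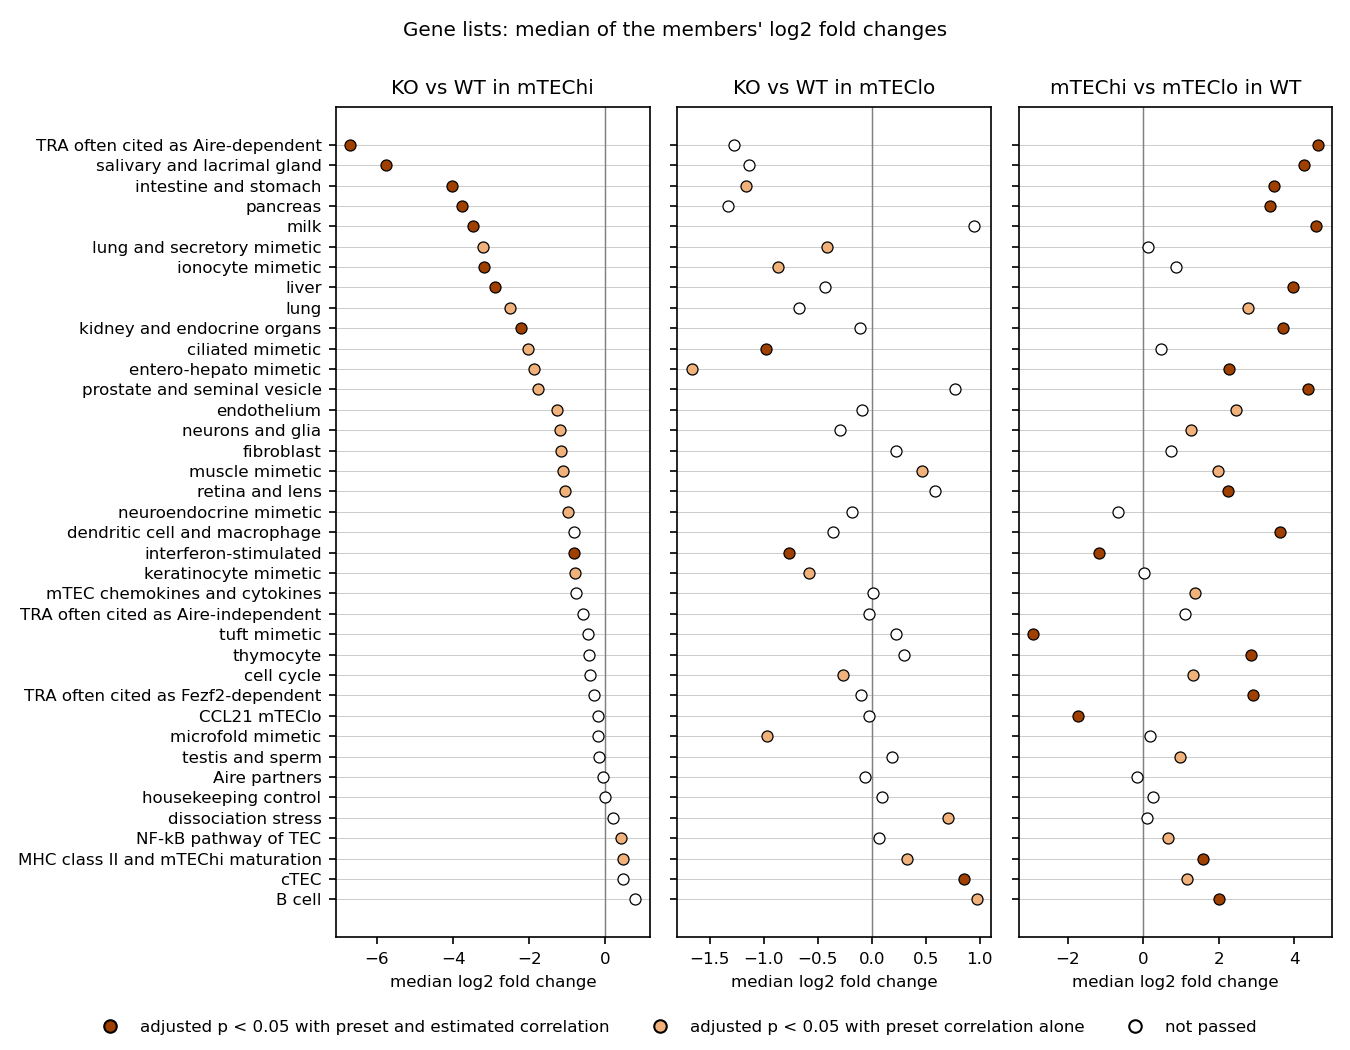
Median log2 change (x axis) of each gene list (y axis) for KO against WT in mTEChi, KO against WT in mTEClo, and mTEChi against mTEClo in WT, with dark points for lists that passed with the preset and an estimated correlation, light ones for the preset alone and white for neither. The mitochondrially encoded list is left out, and the interferon list lay at -0.81, -0.77 and -1.17.

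The same genotypes were compared in mTEClo, where Aire is low. Here ciliated cell and interferon genes fell, and genes of MHC class II, of cortical epithelium and of immediate early stress rose. With an estimated correlation the MHC class II (adjusted p = 0.2) and stress (adjusted p = 0.18) lists did not pass. Replicates 1 and 2 of KO mTEClo, of 5 weeks, differed from 3 and 4, of 6 weeks and without mitochondrial counts, with biological coefficients of variation of 0.217, 0.310, 0.249 and 0.328 between them. Oas3 (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661), an enzyme of antiviral RNA decay, fell from 193 ± 23.3 CPM (n = 8) to 56.2 ± 8.82 CPM (n = 4), a log2 change of -1.74 ± 0.13, adjusted p = 1.3e-10. The T cell inhibitory receptor gene Ctla4 rose here too, from 1.25 ± 1.10 to 15.1 ± 6.05 CPM, a log2 change of 3.54 ± 0.38, adjusted p = 1.8e-07.

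Of ciliated cell genes 12 of 20 measured members fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 change of -0.98 (adjusted p = 7.7e-10; 0.023 with an estimated correlation). The dynein chain Dynlrb2 fell from 5.44 ± 1.46 to 0.270 ± 0.315 CPM and the axoneme gene Spag6l from 9.58 ± 3.55 to 1.64 ± 0.708 CPM. The axonemal dyneins Dnah3 and Dnah12 fell to 0.270 and 0.963 CPM from 31.8 ± 11.98 and 28.4 ± 11.1 CPM, and Cfap65 from 36.5 ± 13.03 to 1.08 ± 0.932 CPM. Rp1, a microtubule protein of photoreceptor cilia, was at least 23.96-fold lower. Ccdc180 was 114-fold (95% counting interval 20.2 to 4512) lower, Spag17 76.004-fold (95% counting interval 13.5 to 3019) lower and Tmem212 55.1-fold (95% counting interval 9.71 to 2194) lower. Spata18 and Sec14l3 were listed at 0 in KO, at least 34.4-fold and 28.4-fold lower. Among 5-week males, with WT replicate 6 (at 4.27, 1.52 and 2.75 CPM) alone against 2 KO libraries at 0.541 CPM or less, Spata18 (adjusted p = 0.075), Sec14l3 (adjusted p = 0.1) and Spag17 (adjusted p = 0.08) did not pass.

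Of interferon-stimulated genes 24 of 27 measured members fell and 1 rose (25 and 1 adjusted over the list alone), with a median log2 change of -0.77 (adjusted p = 4.0e-21; 2.6e-04 with an estimated correlation). Gbp3, an interferon-induced GTPase, fell from 165 ± 10.9 to 64.3 ± 1.60 CPM, and Ifi27, the riser, named after its value was seen, had a log2 change of 0.32 ± 0.10, adjusted p = 0.017. In the entero-hepato list, 11 of 20 measured members fell and 2 rose (12 and 2 adjusted over the list alone), with a median log2 change of -1.67, or -1.45 with members at 0 at their bound (adjusted p = 1.6e-05; 0.14 with an estimated correlation). Of these the acute phase gene Saa1 fell from 15.3 ± 8.09 to 1.22 ± 0.671 CPM, while the intestinal regulator Cdx1 rose from 18.7 ± 2.30 to 41.2 ± 5.42 CPM. In the microfold list, 9 of 13 measured members fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -0.97 (adjusted p = 1.0e-06; 0.14 with an estimated correlation). The peptidoglycan receptor Pglyrp1 fell from 66.3 ± 17.4 to 21.7 ± 4.41 CPM and Serpinb1a from 146 ± 19.3 to 74.03 ± 8.99 CPM. In the ionocyte list, 5 of 12 measured members fell and 0 rose (7 and 0 adjusted over the list alone), with a median log2 change of -0.87 (adjusted p = 7.8e-04; 0.07 with an estimated correlation). Foxi1 had a log2 change of -1.15 ± 0.35, adjusted p = 0.018, which ended without KO replicate 3 (adjusted p = 0.098). Foxi2 had -2.09 ± 0.65, adjusted p = 0.02, which ended without WT replicate 4 (adjusted p = 0.057) or KO replicate 4 (adjusted p = 0.081).

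In the keratinocyte list, 8 of 24 measured members fell and 2 rose (9 and 3 adjusted over the list alone), with a median log2 change of -0.59, or -0.45 with members at 0 at their bound (adjusted p = 0.0017; 0.39 with an estimated correlation). Of intestine and stomach genes 6 of 27 measured members fell and 1 rose (9 and 1 adjusted over the list alone), with a median log2 change of -1.16, or -0.82 with members at 0 at their bound (adjusted p = 0.0033; 0.18 with an estimated correlation). Of lung and secretory genes 4 of 17 measured members fell and 0 rose (4 and 0 adjusted over the list alone), with a median log2 change of -0.42 (adjusted p = 0.009; 0.39 with an estimated correlation). The lung and secretory mimetic list in KO vs WT in mTEClo lost its call without KO replicate 1 (adjusted p = 0.09) or 2 (adjusted p = 0.064). The muscle list rose, and 9 of 23 measured members rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 change of 0.46 (adjusted p = 0.0017; 0.37 with an estimated correlation). The cell cycle list passed downward (adjusted p = 0.038; adjusted p = 0.7 with an estimated correlation) with none of its 24 members passing. The cell cycle list in KO vs WT in mTEClo turned upward among 5-week males, with 1 WT library (adjusted p = 9.9e-04). The mitochondrial list passed downward as well (adjusted p = 6.5e-05; adjusted p = 0.37 with an estimated correlation), with none of 7 members passing. In it mt-Nd2 averaged 71.7 ± 82.9 CPM and mt-Nd6 50.1 ± 58.1 CPM in KO, since 2 of the 4 libraries held no mitochondrial counts.

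Genes of MHC class II and mTEChi maturation rose, and 8 of 20 measured members rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 change of 0.32 (adjusted p = 4.6e-06; 0.2 with an estimated correlation). H2-Ob, part of a regulator of peptide loading, rose from 15.9 ± 3.69 to 36.5 ± 3.24 CPM, and the cytokine receptor chain Il2rg from 6.73 ± 1.61 to 20.4 ± 3.69 CPM. Of cortical epithelium genes 9 of 12 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 change of 0.85 (adjusted p = 1.6e-07; 0.0028 with an estimated correlation). Tbata, a gene of thymic epithelium, rose from 53.6 ± 15.3 to 126 ± 6.76 CPM. Of dissociation stress genes 11 of 17 measured members rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 change of 0.71 (adjusted p = 2.7e-06; 0.18 with an estimated correlation). Dusp1, a phosphatase induced by stress, rose from 47.7 ± 10.2 to 103 ± 12.03 CPM and the stress factor Atf3 from 14.8 ± 2.56 to 35.4 ± 7.23 CPM. Of B cell genes 5 of 9 measured members rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 change of 0.97 (adjusted p = 0.0089; 0.062 with an estimated correlation). The immunoglobulin gene Ighm rose from 8.21 ± 2.55 to 31.6 ± 4.83 CPM.

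The lists of thymocytes (adjusted p = 0.36), dendritic cells and macrophages (adjusted p = 0.84), fibroblasts (adjusted p = 0.4) and endothelium (adjusted p = 0.73) did not pass, nor did the lists of Aire-dependent (adjusted p = 0.58) and Fezf2-dependent antigens (adjusted p = 0.57). Of their members Tcf7 rose from 10.6 ± 2.57 to 24.1 ± 9.11 CPM, the lysozyme gene Lyz2 rose from 34.2 ± 9.04 to 88.9 ± 14.8 CPM, and Fbn1 fell from 529.95 ± 54.3 to 254 ± 43.5 CPM. Tek, a receptor of endothelium, had a log2 change of 0.65 ± 0.19, adjusted p = 0.015, which ended without KO replicate 4 (adjusted p = 0.07). Mucl2 had -1.98 ± 0.65, adjusted p = 0.029, which ended without WT replicate 6 (0.082) or KO replicate 2 (0.056), 3 (0.058) or 4 (0.067). Crp fell from 81.97 ± 15.9 to 30.5 ± 11.4 CPM. Fezf2 (0.20 ± 0.12, adjusted p = 0.25), Cd80 (0.30 ± 0.21, adjusted p = 0.32) and Gad1 (-0.52 ± 0.23, adjusted p = 0.1) did not pass. Gad1 passed without WT replicate 3 (adjusted p = 0.0463) and Cd80 without KO replicate 3 (adjusted p = 0.0484). Ins2 was at 0.407 ± 0.446 CPM in WT and listed at 0 in KO (adjusted p = 0.12), and Ccl21a at 30.04 ± 6.95 and 30.9 ± 10.6 CPM.

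Further large rises were those of the chitinase-like genes Chil3, from 7.05 ± 7.35 to 58.7 ± 11.6 CPM, and Chil4, from 12.1 ± 6.14 to 76.5 ± 35.1 CPM. Lrat, an enzyme that stores vitamin A, rose from 0.872 ± 0.545 to 6.69 ± 0.884 CPM, and the growth factor Fgf10 from 1.28 ± 0.947 to 9.41 ± 4.31 CPM. Stpg3, the cartilage gene Ucma, the protease Tll2 and the neural factor Pou3f3 rose by log2 changes of 3.32, 3.08, 2.67 and 2.59. Among 5-week males, with 1 WT library, the test was not passed by Chil4 (7.32 CPM in WT, 95.8 and 116 in KO, adjusted p = 0.14), Fgf10 (1.83 CPM in WT, 8.12 and 5.01 in KO, adjusted p = 0.069) or Pou3f3 (5.49 CPM in WT, 9.74 and 16.9 in KO, adjusted p = 0.21).

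Between KO and WT mTEClo 4186 of 19310 tested genes changed (21.7%), 2315 upward and 1871 downward. By over 2-fold 825 rose and 681 fell. Of 39 lists 15 passed, 5 upward and 10 downward, and 3 did with an estimated correlation, the interferon, ciliated and cTEC lists. Median, mean and test differed in sign for the Fezf2-dependent, Aire-independent, kidney, chemokine, Aire partner, NF-kB, dendritic cell and endothelium lists, none of which passed. Among 5-week males, where WT replicate 6 stood alone against KO replicates 1 and 2, 1688 genes changed, 1063 of them called the same way with all libraries. With age in the fit 1504 changed, with close pairs merged 2343, with the replicate number as a block 4279 and without the 6 libraries 3938. The genes called the same way without the 6 libraries were 2205, or 52.7% of those called with all libraries.

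The mTEChi and mTEClo of WT mice were compared to describe the populations themselves. Relative to mTEClo, mTEChi were higher for Aire, for tissue genes and for antigen presentation, and lower for tuft cell, CCL21 mTEClo and interferon genes. Aire stood 3.58 ± 0.31 higher on the log2 scale (n = 7 against 8, adjusted p = 2.9e-09), and Fezf2 1.17 ± 0.10 higher. Cd80 averaged 203 ± 12.3 CPM in mTEChi and 20.2 ± 5.18 CPM in mTEClo, Gad1 79.1 ± 11.5 and 8.26 ± 2.61 CPM, Ins2 10.6 ± 4.05 and 0.407 ± 0.446 CPM, and Mucl2 27.2 ± 4.85 and 1.73 ± 1.55 CPM. Ccl21a (7.99 ± 1.77 against 30.04 ± 6.95 CPM) and Crp (14.8 ± 2.97 against 81.97 ± 15.9 CPM) were lower in mTEChi.

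Of tuft cell genes 22 of 23 measured members were lower and 1 was higher (22 and 1 adjusted over the list alone), with a median log2 change of -2.92 (adjusted p = 1.7e-11; 0.031 with an estimated correlation). Gnat3, the G protein of taste cells, averaged 9.51 ± 3.59 CPM in mTEChi and 145 ± 14.4 CPM in mTEClo, and the phospholipase Plcb2 47.3 ± 7.80 and 379.6 ± 41.8 CPM. The largest falls were led by bitter taste receptor genes, near-identical in part. Tas2r102 was 265-fold (95% counting interval 47.3 to 10509.8) lower, Tas2r106 at least 34.9-fold lower and Tas2r105 lower by log2 -6.14 ± 0.30. Tas2r116, Tas2r104, Tas2r118, Tas2r109, Tas2r123 and Tas2r113 averaged 0.0971 to 0.573 CPM in mTEChi and 8.20 to 22.3 CPM in mTEClo. The protocadherin Pcdhb9 was 44.2-fold (95% counting interval 14.9 to 217) lower.

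Of CCL21 mTEClo genes 14 of 15 measured members were lower and 1 was higher (14 and 1 adjusted over the list alone), with a median log2 change of -1.74 (adjusted p = 1.1e-06; 0.031 with an estimated correlation). Lifr, a cytokine receptor, averaged 128 ± 22.8 CPM in mTEChi and 1524 ± 155 CPM in mTEClo, and the growth factor binding protein Igfbp4 20.99 ± 6.999 and 190.4 ± 30.1 CPM. Of interferon-stimulated genes 22 of 27 measured members were lower and 2 were higher (22 and 2 adjusted over the list alone), with a median log2 change of -1.17 (adjusted p = 2.5e-08; 0.012 with an estimated correlation), with the RNA sensor Ddx58 at 61.02 ± 3.43 and 342 ± 16.9 CPM and Gbp3 at 30.9 ± 3.05 and 165 ± 10.9 CPM. Of MHC class II and maturation genes 20 of 20 measured members were higher and 0 were lower (20 and 0 adjusted over the list alone), with a median log2 change of 1.57 (adjusted p = 2.5e-08; 0.0479 with an estimated correlation), with log2 changes of 3.02 ± 0.11 for H2-Ob and 3.56 ± 0.11 for Il2rg.

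Tissue lists were higher in mTEChi, although the testis (adjusted p = 0.044 and 0.072), neurons and glia (0.018 and 0.16) and lung lists (0.015 and 0.055) did not pass with an estimated correlation, whose p is the second of each pair. Members higher were 25 of 27 (25 adjusted over the list alone, adjusted p = 2.8e-08) for intestine and stomach, 22 of 26 (22 adjusted over the list alone, adjusted p = 1.2e-06) for liver, 15 of 15 (15 adjusted over the list alone, adjusted p = 1.2e-06) for prostate and 19 of 20 (19 adjusted over the list alone, adjusted p = 6.4e-06) for the entero-hepato list. The stomach proton pump gene Atp4a averaged 73.9 ± 7.55 and 6.32 ± 1.62 CPM in mTEChi and mTEClo, Pgc 80.9 ± 18.8 and 1.50 ± 1.55 CPM, Itih3 27.1 ± 7.28 and 0.156 ± 0.328 CPM, Itih4 44.7 ± 9.95 and 0.664 ± 0.520 CPM. The surface mucin Muc1 averaged 134 ± 13.6 and 37.3 ± 7.99 CPM, Cdx1 106 ± 26.3 and 18.7 ± 2.30 CPM, and Klk1b26, a kallikrein with near-identical copies, 34.4 ± 5.90 and 0.939 ± 0.675 CPM. Among the largest rises the phosphatase Alppl2, the cholecystokinin receptor Cckar and the bone protein Ibsp were listed at 0 in mTEClo, at least 215-fold, 93.9-fold and 97.3-fold higher in mTEChi. The hormone gene Trh, Mgat4c, Lcn6, Accsl and the water channel Aqp8 were at least 94.96-fold, 76.4-fold, 79.2-fold, 65.9-fold and 67.3-fold higher. The photoreceptor gene Aipl1 was 330.4-fold (95% counting interval 90.996 to 2736) higher, and the cartilage gene Acan went from 0.375 ± 0.592 to 58.3 ± 11.8 CPM.

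Aire-dependent antigens had 9 of 9 (9 adjusted over the list alone, adjusted p = 1.6e-05) higher and Fezf2-dependent antigens 11 of 12 (11 adjusted over the list alone, adjusted p = 3.7e-05), against 5 of 7 (5 adjusted over the list alone, adjusted p = 0.11) for the Aire-independent list, which did not pass. Markers of immune cells were also higher, 14 of 16 (14 adjusted over the list alone, adjusted p = 3.9e-05) for dendritic cells and macrophages, 8 of 9 (8 adjusted over the list alone, adjusted p = 0.0014) for B cells and 9 of 12 (9 adjusted over the list alone, adjusted p = 0.0084) for thymocytes. The chemokine receptor Ccr7 averaged 57.4 ± 12.4 CPM in mTEChi and 2.58 ± 1.53 CPM in mTEClo, the B cell factor Pax5 45.1 ± 8.84 and 4.06 ± 0.784 CPM, and Tcf7 130.4 ± 9.68 and 10.6 ± 2.57 CPM. Endothelium had 7 of 9 (7 adjusted over the list alone, adjusted p = 0.02) higher, with adjusted p = 0.056 with an estimated correlation, and cTEC 8 of 12 (8 adjusted over the list alone, adjusted p = 0.028), with adjusted p = 0.11 with an estimated correlation. Plvap averaged 21.96 ± 7.16 and 1.57 ± 0.532 CPM, and the surface protein gene Cd83 of the cTEC list 50.3 ± 7.97 and 1.75 ± 0.621 CPM. Fibroblast genes did not pass (adjusted p = 0.77), although Fbn1 was lower in mTEChi (103 ± 11.7 against 529.95 ± 54.3 CPM). Alas2, an enzyme of heme synthesis, averaged 23.03 ± 4.75 and 9.63 ± 2.41 CPM.

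In WT 13541 of 19310 tested genes changed (70.1%), 7087 upward and 6454 downward in mTEChi, 1771 of them over 8-fold higher and 226 over 8-fold lower. Of 39 lists 27 passed, 24 upward, and 18 also with an estimated correlation. The Aire partner, dissociation stress and mitochondrial lists, whose median, mean and test differed in sign, did not pass. Among 5-week males, with 1 mTEClo and 3 mTEChi libraries, 9891 genes changed, and with the replicate number as a block 13226.

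The same populations were compared without Aire. The mTEChi of KO mice were again lower for tuft and CCL21 mTEClo genes and higher for MHC class II genes, though none of these lists passed with an estimated correlation, and the Aire-dependent antigens did not pass, with 1 higher and 1 lower of 9, or 1 and 1 adjusted over the list alone (adjusted p = 0.9). The matrix receptor Antxr1 averaged 8.90 ± 2.67 CPM in mTEChi and 333 ± 13.3 CPM in mTEClo (n = 4 each), a log2 change of -5.21 ± 0.14, adjusted p = 2.0e-21. The actin-binding protein Cald1 (23.4 ± 2.49 and 299 ± 11.9 CPM) and the cytokine receptor Il6st (63.7 ± 7.49 and 659.9 ± 35.5 CPM) were lower too. The molybdenum enzyme Marc1 (242 ± 8.03 and 17.2 ± 1.96 CPM), the synapsin Syn2 (413 ± 22.6 and 41.6 ± 5.30 CPM) and the calcium pump Atp2b4 (578 ± 51.8 and 108 ± 5.93 CPM) were higher.

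Of tuft genes 22 of 23 measured members were lower and 1 was higher (22 and 1 adjusted over the list alone), with a median log2 change of -3.37, or -3.33 with members at 0 at their bound (adjusted p = 1.2e-13; 0.057 with an estimated correlation). Of CCL21 mTEClo genes 13 of 15 measured members were lower and 1 was higher (13 and 1 adjusted over the list alone), with a median log2 change of -2.15 (adjusted p = 3.5e-06; 0.096 with an estimated correlation). Of MHC class II genes 19 of 20 measured members were higher and 0 were lower (20 and 0 adjusted over the list alone), with a median log2 change of 1.77 (adjusted p = 3.4e-09; 0.096 with an estimated correlation). Of the Fezf2-dependent antigens 10 of 12 measured members were higher and 0 were lower (10 and 0 adjusted over the list alone), with a median log2 change of 2.98 (adjusted p = 1.4e-04; 0.057 with an estimated correlation). Of interferon genes 22 of 27 measured members were lower and 5 were higher (22 and 5 adjusted over the list alone), with a median log2 change of -1.21 (adjusted p = 2.4e-07; 0.055 with an estimated correlation). In this contrast 11039 of 19310 tested genes changed (57.2%), 5630 upward and 5409 downward. Of 39 lists 11 passed, 7 upward and 4 downward, and 0 did with an estimated correlation. Among 5-week males 9380 genes changed, with close pairs merged 10137, and with the replicate number as a block within KO 9283.

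The KO effect was tested for a difference between the gates, since Aire is far higher in mTEChi. The differences with the smallest p were those of genes of matrix and cell contact downward, and of a lipoprotein receptor, a phosphatase and a chemokine upward. Sparc, a collagen-binding matrix protein, averaged 79.1 ± 7.66 CPM in WT and 2.42 ± 0.924 CPM in KO mTEChi, and 109 ± 13.1 and 123 ± 19.5 CPM in mTEClo, a log2 difference of -5.16 ± 0.23, adjusted p = 1.3e-15. The fibulin Fbln2 and the neurexin Nrxn3 had differences of -8.52 ± 0.50 and -5.92 ± 0.35. Upward, the lipoprotein receptor Lrp1b averaged 97.1 ± 11.2 and 211 ± 66.5 CPM in WT and KO mTEChi and 128 ± 8.37 and 34.9 ± 3.48 CPM in mTEClo, a difference of 3.01 ± 0.19, adjusted p = 6.9e-12. The phosphatase Ptpn14 and the chemokine Cxcl16 had differences of 1.42 ± 0.13 and 1.39 ± 0.12.

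The Aire-dependent antigens fell further in mTEChi, with 4 of 9 members differing downward, 4 adjusted over the list alone (adjusted p = 1.4e-08; adjusted p = 4.0e-04 with an estimated correlation). In mTEClo 5 of the 9 were at 0 in a group and had little room to fall. Salivary, pancreas, liver and intestine genes did as well, with 3 of 10, 4 of 17, 12 of 26 and 5 of 27 members (3, 6, 12 and 8 adjusted over the list alone) and adjusted p of 5.0e-07, 2.9e-06, 5.8e-07 and 5.0e-07. The muscle list, which rose in mTEClo and fell in mTEChi, had 14 of 23 members differing downward, 14 adjusted over the list alone (adjusted p = 5.8e-07; adjusted p = 0.057 with an estimated correlation). The NF-kB list differed upward in 8 of 20, 9 adjusted over the list alone (adjusted p = 2.3e-04; adjusted p = 0.22 with an estimated correlation). The interferon list did not pass (adjusted p = 0.96), with 10 members differing downward and 6 upward of 27 (10 and 6 adjusted over the list alone).

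The difference passed for 4792 of 19310 genes (24.8%), 2699 downward and 2093 upward. Of genes lower in both gates there were 1127, against 523 if the calls were independent, and of genes higher in both 1395 against 595. Those of opposite direction numbered 265 and 116, against 647 and 481. By over 2-fold in both gates, 128 were lower in mTEChi and higher in mTEClo, against 144. Across genes, which are not independent replicates, the changes in the 2 gates had a Pearson correlation of 0.431 and a Spearman correlation of 0.434. Of 39 lists 24 passed, 22 downward, 11 also with an estimated correlation. Among 5-week males, with 1 WT mTEClo library, 2478 genes differed, with close pairs merged 2937 and with the replicate number as a block 4392.

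Sex was compared within the WT libraries, 5 of females and 10 of males. Genes of the sex chromosomes made up the calls. Xist, the RNA that silences an X chromosome, was higher in females by 7.16 ± 0.13 on the log2 scale (adjusted p = 3.7e-25). The X-linked demethylase genes Kdm6a (0.66 ± 0.078, adjusted p = 1.0e-05) and Kdm5c (0.45 ± 0.078, adjusted p = 0.009) were higher as well. Kdm5c did not pass without WT mTEChi replicate 4 (adjusted p = 0.13) or 5 (adjusted p = 0.076). The Y-linked genes Uty (-10.32 ± 0.42), Kdm5d (-9.81 ± 0.41) and Ddx3y (-9.57 ± 0.48) were lower, as were Eif2s3y (-10.79 ± 0.58) and Usp9y (-5.90 ± 0.96), named after their values were seen. In edgeR 8 genes passed, with 690 at an unadjusted p under 0.05. With the replicate number as a block 5 passed.

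**Figure D5:**
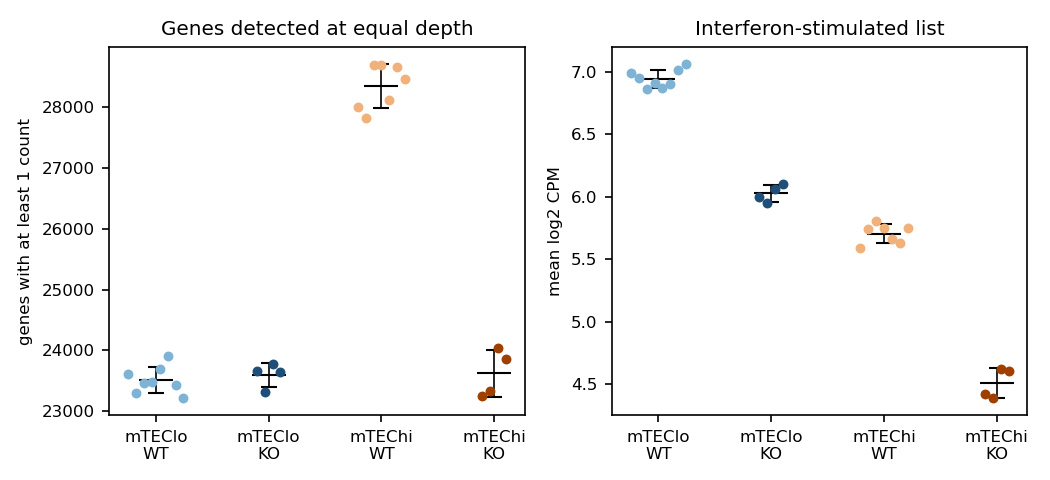
Genes detected at an equal depth of 1590514 counts per library and, in the other panel, mean log2 CPM of the 27 interferon-stimulated genes, by group with points for libraries and bars for mean and SD. Detection averaged 28352 genes in WT and 23619 in KO mTEChi.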

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

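The tests of the 3 patterns weighed in this part were chosen only after the results they address were seen, while the tests of single libraries and of a difference between the gates were set before. The difference of the KO effect between the gates passed for 4792 genes, and for 53 of those named and 24 lists, which are given here as the effect in mTEChi minus that in mTEClo.

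Among genes of peripheral tissues and their mimics the log2 differences were -4.38 for Foxi1, -4.05 for Itih4, -3.74 for Muc6 and -1.29 for Slc12a2. Genes with at most 3 counts in KO mTEChi had fitted differences of -11.39 for Sst, -10.60 for Muc16, -9.52 for Krt13, -8.52 for Fbln2 and -4.91 for Mucl2, which are no bounds. Other differences below -2 were -6.69 for Chil3, -5.92 for Nrxn3, -5.16 for Sparc, -4.97 for Tll2, -4.75 for Chil4, -4.72 for Adgre1, -4.63 for Enpep, -4.48 for Plvap, -4.23 for Ucma and -2.14 for Ifit2. Smaller ones downward were -1.83 for Stpg3, -1.50 for Pou3f3, -1.32 for Lrat, -1.15 for Gbp2, -1.13 for Ighm, -1.01 for Atf3, -0.92 for Cd80, -0.80 for Lyz2, -0.80 for Gbp3, -0.78 for Dusp1, -0.78 for Il2rg, -0.60 for Tbata and -0.45 for Fbn1. Upward they were 5.25 for Rp1, 3.01 for Lrp1b, 2.89 for Dnah12, 2.30 for Spag6l, 2.22 for Ptchd4, 1.86 for Crp, 1.42 for Ptpn14, 1.39 for Cxcl16, 0.93 for Oas3, 0.80 for Pglyrp1 and 0.57 for Serpinb1a. Of the split genes, Med10 had a fitted difference of -9.84, and the mitochondrial genes had -13.62 for mt-Rnr2, -12.85 for mt-Rnr1, -12.33 for mt-Nd5, -12.17 for mt-Cytb, -11.98 for mt-Co1, -11.76 for mt-Nd1, -10.90 for mt-Nd4, -10.51 for mt-Nd2 and -10.11 for mt-Nd6.

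Of the lists, those that passed with an estimated correlation as well had adjusted p of 1.4e-08 for Aire-dependent antigens, 5.0e-07 for salivary and lacrimal gland, 2.9e-06 for pancreas, 5.8e-07 for liver, 1.4e-06 for prostate and seminal vesicle, 1.9e-04 for milk, 9.8e-05 for retina and lens, 5.0e-07 for intestine and stomach, 2.4e-05 for kidney and endocrine organs, 0.0036 for fibroblast and 0.0036 for endothelium. The others did not pass with an estimated correlation, whose p is the second of each pair. Their adjusted p were 0.034 and 0.26 (neurons and glia), 0.044 and 0.14 (lung), 0.017 and 0.5 (tuft), 0.0058 and 0.32 (microfold), 5.8e-07 and 0.057 (muscle), 0.044 and 0.39 (neuroendocrine) and 0.0041 and 0.064 (ionocyte). For the rest they were 0.01001 and 0.32 (lung and secretory), 2.3e-04 and 0.22 (NF-kB), 0.034 and 0.3 (dendritic cell and macrophage), 0.0043 and 0.0529 (cTEC), 0.044 and 0.56 (dissociation stress) and 0.015 and 0.5 (mitochondrially encoded). The microfold and NF-kB lists differed upward and the others downward.

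A single library lay apart from the rest of its group in 6 of 258 tests of named genes, where chance alone would give about 12.9. The gap to the nearest library, divided by the range of the group, exceeded the 95% limit for Alas2 in WT mTEClo replicate 7 (14.8 CPM, next 10.2, other end 6.89, ratio 0.577), Mucl2 in WT mTEClo replicate 6 (5.19 CPM, next 2.30, other end 0.2998, ratio 0.591), Myh8 in WT mTEChi replicate 6 (59.4 CPM, next 42.5, other end 32.7, ratio 0.633), Ptchd4 in WT mTEChi replicate 2 (12.001 CPM, next 17.7, other end 18.7, ratio 0.847), Ptpn14 in KO mTEChi replicate 4 (774 CPM, next 795, other end 799, ratio 0.872) and Slc4a1 in WT mTEClo replicate 1 (8.62 CPM, next 1.22, other end 0, ratio 0.858). Replicate 6 of WT mTEClo was among the libraries without which the fall of Mucl2 in mTEClo did not pass (adjusted p = 0.082).

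All 4 KO mTEChi libraries and 2 of KO mTEClo held no mitochondrial counts, and 33 nuclear genes split with them. Loss of mitochondrial RNA in KO cells is argued against by replicates 1 and 2 of KO mTEClo, which held 0.3305 and 0.377% mitochondrial counts. Counting against another annotation or rule in these libraries may be the source, since 54.5% of the nuclear split genes overlapped another gene on their strand, against 25.6% of other tested genes (odds ratio 3.48, Fisher's exact test, two-sided, p = 4.4e-04). In mTEChi this division of the libraries was also that of genotype, so that for the split genes the effect of Aire there stays open.

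Many more genes fell than rose by over 2-fold in KO mTEChi (3381 genes). In the 2269 of these with a mean of at least 1 CPM in KO mTEClo, the median difference there between replicates with and without the feature was 0.19 (quartiles -0.33 and 0.73), but these replicates were also of 6 and of 5 weeks, so that an opposite effect of age could hide one of processing. With age and a term for the 6 libraries fitted, the genes kept a median log2 change of -2.10 in mTEChi (quartiles -3.31 and -1.25), against -1.83 without, which argues against processing as the whole cause if age acts alike in both gates, although the same fit turned Aire in KO vs WT in mTEChi to 0.13. Of them 69.5% were still called lower, and for the others, and for genes hardly counted in mTEClo, processing stays open. Close library pairs counted as separate samples are argued against by the 93.1% of the genes still called lower with pairs merged, and loss of Aire and the age of the KO mice may both contribute.

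Interferon-stimulated genes were lower in KO mTECs of both gates. In mTEClo the median log2 change of -0.94 without the 6 libraries (25 of 27 lower) argues against processing. For mTEChi it stays open, as no KO library is left. In mTEChi the median of -0.94 among 5-week males (24 of 27 lower) argues against age. Each test rests on a close pair of KO libraries. All 8 KO libraries had a list mean below every WT library of the gate. Aire genotype is a candidate, found and tested on the same libraries. Housing and infection were not tested.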

How the results depend on the processing

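The merging of close library pairs, the fits without the 6 libraries or with a term for them, the removal of split genes and the list tests among 5-week males were chosen only after the results were seen. Under upper quartile factors the median log2 change of all genes was -0.125 for KO in mTEChi and -0.116 for the difference between the gates, and changes there are relative to it. Fits of KO in mTEChi, of the gates in KO or of the difference without the 6 libraries could not be made, because no KO mTEChi library remains, and every other alternative set beforehand was run. With 1 library left out the remaining ones of a group were pooled with the other groups for the spread.

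With a change of over 2-fold required, the genes changed were 4492 for KO in mTEChi, 1506 for KO in mTEClo, 6937 for the gates in WT, 6779 for the gates in KO and 2614 for the difference, since fewer genes meet both limits. At an adjusted p under 0.01 they were 2240 for KO in mTEClo and 2856 for the difference. KO in mTEClo gave 1504 genes with age fitted, 1688 among 5-week males, 2343 with pairs merged and 2522 with age and a term for the 6 libraries. The difference gave 2478 among 5-week males and 2937 with pairs merged. Among 5-week males WT mTEClo was replicate 6 alone, assumed to vary like the other groups, with pairs merged fewer samples were fitted, and for age the cause was not tested. With the term for the 6 libraries 6872 genes changed for KO in mTEChi. With the replicate number as a block, 5 genes passed for sex. The cause was not tested. Under all other alternatives the counts of genes lay within 1.5 times those reported.

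Without each library in turn the genes changed numbered 9623 to 10844 for KO in mTEChi, 3126 to 4290 for KO in mTEClo, 12838 to 14201 for the gates in WT, 10557 to 11221 for the gates in KO, 4234 to 4832 for the difference and 6 to 9 for sex. The lists that passed numbered 23 to 24, 14 to 16, 27 to 27, 10 to 13 and 19 to 24 in the first 5 of these. With an estimated correlation 9, 3, 18, 0 and 11 lists passed. For the gates in KO 20 lists passed with no filter and 29 with fry, which tests a list on its own. The cause was not tested for the filter.

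Some lists turned. The cell cycle list in KO vs WT in mTEClo turned upward with age (adjusted p = 0.079), among 5-week males (1 WT library, 9.9e-04), without the 6 libraries (7.3e-05), and with a term for them without (7.1e-04) or with age (6.9e-06). Without single libraries its adjusted p ran from 1.1e-06 to 0.92, the highest, with the sign turned, without KO mTEClo replicate 4. It did not pass without WT mTEClo replicate 1, 2 or 6 or KO mTEClo replicate 3 (0.058, 0.065, 0.07 and 0.38). The NF-kB pathway of TEC list in KO vs WT in mTEClo, which did not pass, turned among 5-week males (1 WT library, 0.0018), without the 6 libraries (0.0065) and with the term without (0.014) or with age (0.0088). The mitochondrially encoded list in KO vs WT in mTEClo turned among 5-week males (0.203) and with age and the term (0.296). With the term, without and then with age, the cell cycle list in KO vs WT in mTEChi turned (9.5e-07 and 1.3e-06), as did the cell cycle list in KO effect in mTEChi minus KO effect in mTEClo (2.8e-05 and 9.5e-04). The MHC class II and mTEChi maturation list in KO effect in mTEChi minus KO effect in mTEClo turned without age (0.045). The cause was not tested.

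The term for the 6 libraries is estimated in KO mTEClo alone, where replicates 3 and 4 were also of 6 weeks and 1 and 2 of 5, so that a gene near 0 there gives it an uncertain size. With it, without and then with age, the log2 change in KO mTEChi turned to 0.0933 and 0.0900 for mt-Rnr2 in KO vs WT in mTEChi, 0.14 and 0.14 for mt-Rnr1 in KO vs WT in mTEChi, 0.14 and 0.13 for Med10 in KO vs WT in mTEChi, 0.0878 and 0.13 for Aire in KO vs WT in mTEChi, 0.53 and 0.53 for Cd80 in KO vs WT in mTEChi, -0.29 and -0.27 for Crp in KO vs WT in mTEChi, -2.14 and -2.05 for Ptgs2os2 in KO vs WT in mTEChi, -0.45 and -0.54 for Sssca1 in KO vs WT in mTEChi and -2.85 and -2.97 for B4gat1 in KO vs WT in mTEChi. With age it also turned to -0.10 for Chtf8 in KO vs WT in mTEChi. None of these passed under the term.

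Leaving out single libraries, given by group and replicate with adjusted p, ended the neuroendocrine mimetic list in KO effect in mTEChi minus KO effect in mTEClo without WT mTEClo 1, 2, 7, 8, KO mTEClo 3, 4, WT mTEChi 2, 3, 5 and KO mTEChi 1, 2, 3 (0.0504 to 0.21). It also ended the dissociation stress list in KO effect in mTEChi minus KO effect in mTEClo without WT mTEClo 3, 4, 6, 7, 8, KO mTEClo 3, 4, WT mTEChi 3, 5, 7 and KO mTEChi 1, 2 (0.0504 to 0.15). Others that ended were the lung list in KO effect in mTEChi minus KO effect in mTEClo without WT mTEClo 6, 8, KO mTEClo 3 and WT mTEChi 3 (0.0501 to 0.066), the dendritic cell and macrophage list in KO effect in mTEChi minus KO effect in mTEClo without KO mTEClo 1, 3 and KO mTEChi 3 (0.055 to 0.067), the mitochondrially encoded list in KO effect in mTEChi minus KO effect in mTEClo without KO mTEClo 1, 2 (0.062 to 0.067) and the tuft mimetic list in KO effect in mTEChi minus KO effect in mTEClo without KO mTEClo 3 (0.0511).

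Of 1007 values of named genes in KO mTEChi under alternatives other than leaving out libraries, 927 kept their direction and side of the threshold, as did 792 of 827 in KO mTEClo and 866 of 866 for the gates in WT. In KO mTEChi 24 of 63 genes and 16 of 39 lists never changed. Of the gene values there 59 lost their call and 19 turned, nearly all with the term for the 6 libraries. Of list values 426 of 468 did in KO mTEChi and 454 of 507 in KO mTEClo. Depth and replicate number limit small changes. In simulated data of these sizes 35.8% of genes changed 1.5-fold and 77.6% of those changed 2-fold were called for KO in mTEChi. For the difference between the gates 10.4% and 65.7% were called.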

Other observations

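The count of detected genes was chosen as a test only after the result was seen, and the tests of neighbouring genes and of other splits were set before. At an equal depth of 1590514 counts, WT mTEChi expressed the broadest set of genes of the 4 groups, 28352 ± 367 (SD, n = 7), against 23619 ± 387 in KO mTEChi (n = 4). WT mTEClo held 23511 ± 219.6 (n = 8) and KO mTEClo 23593 ± 195 (n = 4). In two-sided exact permutation tests, KO and WT differed in mTEChi (p = 0.003, the smallest possible for separate libraries) and the gates differed in WT (p = 1.6e-04, the smallest possible). By the same exact permutation test KO and WT did not pass in mTEClo (p = 0.53), nor did the gates in KO (p = 0.91). The highest KO mTEChi library held 24039 genes and the lowest of WT 27822, and all KO mTEChi libraries were among the 6 without mitochondrial counts.

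Genes that fell over 8-fold in KO mTEChi lay beside one another on chromosomes more often than chance gave. Among the 1216 such genes that are not mitochondrial there were 170 neighbouring pairs with unlike names, against a mean of 65.4 and a 95% limit of 78 in 10000 draws of genes matched in expression (permutation p = 1e-04, the smallest these draws can give). With pairs of like names counted too there were 290. Shared chromosomal neighbourhoods may therefore link part of these genes, and overlapping transcripts of unlike names were not separated from true neighbours.

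Other splits of the libraries into groups of the same sizes were tested. With libraries taken as separate samples, chance can be excluded for KO in mTEChi, where 1 of 100 splits, the real one with 10366 genes, reached that count and the highest other called 2773. With close pairs merged 2 KO and 4 WT samples remain in mTEChi, and 2 and 3 for the gates in KO, too few for a share or an exact p under 0.05. For separate libraries it can be excluded too for KO in mTEClo (4186 genes, highest other 823) and the difference between the gates (4792, highest other 1700). The same holds for the gates in KO (11039, highest other 1303 of 35 splits) and in WT (13541, highest other 12082, in a split that kept 7 of 8 mTEClo libraries together). For sex 3 of 100 splits, the real one included, gave at least 8 genes, and the highest other called 18. The count alone cannot exclude chance for sex. The split with 18 put replicates 1 and 2 of WT mTEClo and 1 to 3 of WT mTEChi together, 4 of which were from mice of 4 weeks. With age fitted 8 genes passed for sex.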
